A study of Mus musculus with 4 samples.

How the data were processed

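H3K27me3, a histone mark of Polycomb repression, was mapped by CUT&Tag, in which an antibody-guided transposase cuts and tags the DNA around the mark. The 4 libraries came from sorted splenic germinal center B cells of C57BL/6 mice, 2 wild type (WT) and 2 with a B-cell knockout (KO) of Kdm6b, and each library came from a separate mouse per the series description. Per the labels' protocols, mice were immunised with sheep red blood cells, boosted on day 5 and killed on day 12, and 1000 to 5000 cells per library were incubated with 1 µg of antibody. The labels name the cells as germinal center B cells and the series title adds the term pre-plasma. The sort markers behind that term, the sex of the mice and the deleted part of Kdm6b are not given in the sources used here.

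Each library had its own deposited peak list with 6 columns, giving the position of each peak, its total signal, its highest signal and the place of that highest signal. The authors deposited these values as signal (coverage), called per library and not on pooled samples. Per the submitters' processing notes, the reads were handled with Trim Galore 0.6.6, Bowtie2 2.4.2, SAMtools 1.11, SEACR and deepTools on the mm10 build. The role and settings of each tool, the control and threshold used for peak calling and the scale of the signal are not given in the sources used here. Within each list the highest signals were whole multiples of a step, which was 9.43 in KO replicate 1, 9.90 in KO replicate 2, 8.40 in WT replicate 1 and 11.4 in WT replicate 2. Between 99.98% and 99.998% of maxima met this within 0.001 steps. The lowest maximum in a list was 20 steps in KO replicate 1, 13 in KO replicate 2, 20 in WT replicate 1 and 22 in WT replicate 2. Because the scale behind these steps is unknown, signal was used to rank peaks within a list and, in units of steps, to describe coverage, and it was not tested between genotypes. Read depth was unknown, so no counting interval was computed. The precision of the permutation comparisons rests on the spread between 2 mice per genotype. For limma, eBayes draws the spread of each gene end or window towards a value shared by all of them.

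Peaks on chromosomes 1 to 19, X and Y were kept. The 4 lists were merged into 117983 regions wherever peaks overlapped or touched, and a library had a region if its peaks overlapped it by at least 1 bp. The genome was also divided into 10 kb windows, and the share of each window covered by peaks was computed per library. The gene annotation was RefSeq on GRCm38.p6, the assembly that mm10 denotes, with 21887 protein-coding genes. The annotation table gives no strand, so the planned promoter window at the 5′ end could not be placed. In its place a gene-end window was used, from 2000 bp before to 2000 bp after whichever end of the gene had the higher mean covered share over all 4 libraries. This choice uses no genotype label, but for some genes the window lies at the 3′ end. A gene end was called marked in a library where peaks covered at least 25% of its 4000 bp. Exon, intron and UTR positions were not used here.

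The groups, the rule for naming genes and 16 gene lists were fixed before the data were examined. So were the permutation, limma and camera tests, the counts over splits and most alternatives. The alternatives of equal covered length, the covered length of each library as a covariate, and both gene ends averaged were added after the data were seen. For the lists the plan held camera and a description of marked shares, so the Fisher's exact tests were not fixed in advance. Peak number, covered length and X share were compared by exact two-sided permutation of the 6 relabellings, for which the smallest possible p is 0.333. Counts of regions or gene ends present in both libraries of one genotype and neither of the other were set beside the same counts for the other splits of the libraries, 3 in all. Covered shares of windows and gene ends were compared with limma 3.58.1 (lmFit and eBayes, without trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Windows or gene ends with no coverage in any library were left out. The gene lists were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, and the marked share of each list in each library was compared with that of all other genes by Fisher's exact test (64 tests, Benjamini-Hochberg adjusted). All 450 listed symbols were found in the annotation. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

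Named genes were Kdm6b, a fixed set of B-cell and Polycomb genes, and for each direction 12 genes. As no gene end passed limma, these 12 were taken from genes marked in both libraries of one genotype and neither of the other, by the size of the difference. Predicted genes and olfactory, vomeronasal and taste receptors were passed over. List members with such a pattern and the 5 longest regions per direction could also be named. Some genes under this rule are not reported here. Other genes named below were chosen after their values were seen.

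The alternatives were a stricter list without the lowest 25% of peaks by total signal, lists of equal peak number, autosomes only, other overlap, merging, window and filter settings, an arcsine scale, eBayes with trend, gene bodies, and leaving out each library in turn. Equal covered length kept, in each library, the peaks with the highest mean signal per base down to the covered length of the shortest list. It kept 50002 peaks in KO replicate 1, 22255 in KO replicate 2, 28616 in WT replicate 1 and all 82292 in WT replicate 2, so it removes the lower peaks of the broad lists. The limma step was tested on simulated data made from the real covered shares. Noise was the scaled difference between KO replicate 2 and WT replicate 1, shuffled across genes or windows. It therefore holds any genotype difference between them and is not the spread within genotypes. With the full noise, 0% of 100 gene ends given a change of 60 points were called among 13844, with a mean estimate of 58.0 points and 0 false calls. With 20% of that noise, 98% of such gene ends were called. For the 68542 windows, 0% of 100 windows changed by 60 points were called with the full noise and 100% with 20% of it. A change of 20 points added to the NF-kB list gave a camera adjusted p of 3.28e-07 over 13844 gene ends, and 0 of the other 15 lists were called. Shuffling left the simulated genes uncorrelated, while the estimated correlation of this list in the data was 0.524. The simulation thus does not show what camera can detect in these data.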

Results

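The data were 4 genome-wide maps of H3K27me3 in splenic germinal center B cells, the cells in which activated B cells mutate their antibody genes and from which plasma cells and memory B cells arise. They compared 2 WT mice with 2 mice lacking Kdm6b in B cells. Kdm6b, also called JMJD3, removes methyl groups from H3K27, so the comparison asks where the mark differs when this enzyme is lost. The peak lists held 80639 peaks in KO replicate 1, 90417 in KO replicate 2, 87486 in WT replicate 1 and 82292 in WT replicate 2 on chromosomes 1 to 19, X and Y. Replicate numbers only name the libraries. Read depth was unknown. The permutation p-values rest on the spread between these mice. The limma p-values and SEs rest on that spread drawn towards a value shared by all gene ends or windows. Fisher p-values count genes within a single library and hold no spread between mice, and the Fisher tests were not fixed in advance. At the preset correlation, camera takes the genes of a list as nearly independent.

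The targeted gene itself carried H3K27me3 in every library. Kdm6b (gene ID 216850) lies on chromosome 11 at 69398508 to 69420367 in mm10. Peaks covered 41.3% of its body in KO replicate 1, 66.6% in KO replicate 2, 49.6% in WT replicate 1 and 36.7% in WT replicate 2. Its gene-end window, at the higher coordinate, was covered to 100% ± 0 in KO and 90.2% ± 13.9 in WT (SD, n = 2). Of the 21860 bases of the gene, 5367 were covered in all 4 libraries, 202 in both KO and neither WT, and 0 in both WT and neither KO. A map of H3K27me3 peaks does not show which exons were deleted, so these values do not check the genotype.

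The mark was spread over different lengths of genome in the 4 libraries, and the difference between mice of one genotype exceeded that between genotypes. Peaks covered 144 Mb in KO replicate 1, 236 Mb in KO replicate 2, 213 Mb in WT replicate 1 and 101.4 Mb in WT replicate 2. The genotype means were 190 ± 65.0 Mb in KO and 157 ± 78.6 Mb in WT (SD, n = 2 each, exact permutation p = 0.667). Median peak width followed the same order, at 1140, 1557, 1512 and 861 bp. Peaks longer than 5 kb held 26.3% of the covered length in KO replicate 1, 40.1% in KO replicate 2, 36.1% in WT replicate 1 and 13.9% in WT replicate 2. Peak number was 85528 ± 6914 in KO and 84889 ± 3673 in WT (exact permutation p = 1.0).

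**Figure D1:**
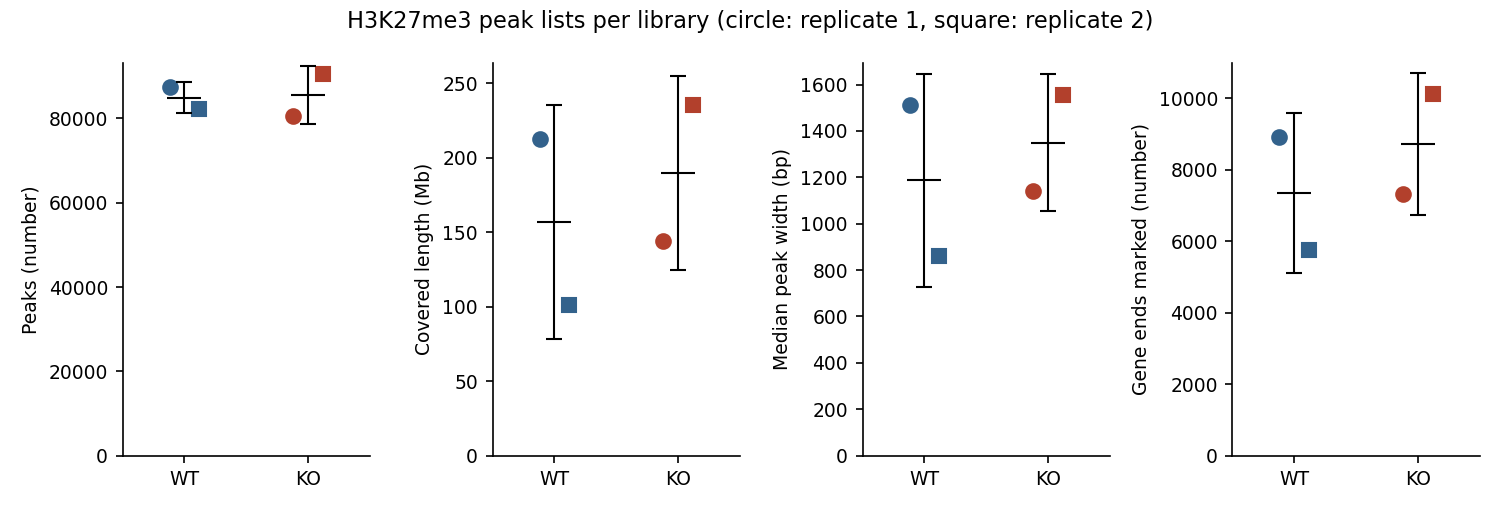
Number of peaks, covered length in Mb, median peak width in bp and number of marked gene ends for each H3K27me3 library, with WT in blue and KO in red. Points are single libraries (circle replicate 1, square replicate 2) and bars are the mean and SD of 2 mice. Covered length runs from 101.4 to 236 Mb and the genotypes overlap in every panel.

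Which libraries were most alike depended on the measure. The shared length divided by the combined length was 0.574 for KO replicate 2 and WT replicate 1, against 0.465 for the KO pair and 0.350 for the WT pair. That ratio is limited by unequal covered length, and KO replicate 2 and WT replicate 1 were the broadest lists. As a share of the shorter list, the overlap was 83.7% for the KO pair, 83.4% for KO replicate 2 and WT replicate 2, 80.3% for the WT pair and 76.9% for KO replicate 2 and WT replicate 1. It was 79.7% for KO replicate 1 and WT replicate 1 and 67.3% for KO replicate 1 and WT replicate 2. This share can rise where a short list is set against a broad one. The correlation of window shares was highest for KO replicate 2 and WT replicate 1, at 0.886, against 0.852 for the KO pair and 0.789 for the WT pair. Of the 117983 merged regions, 26992 (22.9%) were called in all 4 libraries, and these had a median length of 4635 bp and spanned 177 Mb. The X chromosome held 0.900% ± 0.0404 of covered length in KO and 0.814% ± 0.0702 in WT (SD, n = 2, exact permutation p = 0.33, the smallest possible). That difference of 0.0866 percentage points became -0.0199 at equal covered length. The Y chromosome had 2 to 4 peaks per library.

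In every library, H3K27me3 lay over the genes that specify body axis and other lineages and was sparse over the germinal center program. Of 39 Hox genes, which pattern the body axis, 39 gene ends were marked in each KO library and in WT replicate 1, and 38 in WT replicate 2. Of 80 developmental transcription factors, 79 were marked in both KO libraries, 78 in WT replicate 1 and 76 in WT replicate 2. Of 36 germinal center B genes, 5 and 7 were marked in the KO libraries and 6 and 3 in the WT libraries. Against 33.5%, 46.3%, 40.8% and 26.3% of all 21887 genes in KO replicates 1 and 2 and WT replicates 1 and 2, Hox genes and developmental factors were marked more often in 4 of 4 libraries by Fisher's exact test (highest adjusted p = 6.83e-13 and 2.16e-24). Germinal center B genes were marked less often in 4 of 4 (Fisher's exact test, highest adjusted p = 0.0441). The test takes genes as independent, but 1 long peak can mark neighbouring genes together. The longest peak per library was 26015 to 84493 bp.

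Of the lists for other blood cells that a splenic sort could hold, the myeloid list passed the same test. Myeloid genes were marked more often than all genes in 4 of 4 libraries, at 17, 20, 22 and 15 of 27 (highest adjusted p = 0.0245, Fisher's exact test). Among them, the receptor gene Cd14 was covered to 100% in every library. T cell genes were marked at 14, 17, 17 and 12 of 27, NK cell genes at 4, 9, 7 and 4 of 15, and erythroid genes at 10, 11, 11 and 9 of 17, and none of these lists passed in any library. Single members chosen after their values were seen, namely Gata3, a T cell transcription factor, Eomes of NK cells and Tal1 of the erythroid lineage, were covered to 100% in every library. Mean marked shares of the myeloid list were 68.5% ± 7.86 in KO and 68.5% ± 18.3 in WT (SD, n = 2).

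Among genes that steer B cell fate, the plasma cell genes Prdm1 and Sdc1 were marked in all 4 libraries, while Irf4 and Xbp1 were marked in KO replicate 2 alone. Prdm1, which encodes the plasma cell factor Blimp-1, was covered to 83.8% ± 2.74 in KO and 73.8% ± 18.1 in WT (SD, n = 2 here and for the genes that follow). Sdc1, the plasma cell surface protein CD138, was covered to 97.8% ± 3.13 and 82.4% ± 24.9. Irf4, which acts with Blimp-1 in plasma cell formation, had 26.2% ± 13.7 and 10.8% ± 15.3, and Xbp1, a driver of the secretory program, had 27.9% in KO replicate 2 and 0% elsewhere. The germinal center regulator Bcl6 had no coverage in any library, and the B cell factors Pax5 and Bach2 reached at most 10.2% and 8.80%. The chemokine receptor gene Cxcr4 had 47.7% in KO replicate 2 and 0% elsewhere, and the H3K27 methyltransferase gene Ezh2 had 10.8% there and 0% elsewhere. Kdm6a, the X-linked H3K27 demethylase, had 10.6% ± 14.9 and 8.30% ± 11.7.

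Cdkn2a, a cell cycle inhibitor gene and well-known Polycomb target, was covered to 100% in all 4 libraries. The migration genes Klf2 and S1pr1, which act in the exit of lymphocytes from lymphoid tissue, were covered to 96.6% ± 4.77 and 78.3% ± 13.7 in KO and to 57.3% ± 47.7 and 60.7% ± 2.55 in WT. The limma adjusted p was 0.895 for both. For Klf2 a single library held the WT mean down, with 23.6% in WT replicate 2 against 91.1% in WT replicate 1.

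**Figure D2:**
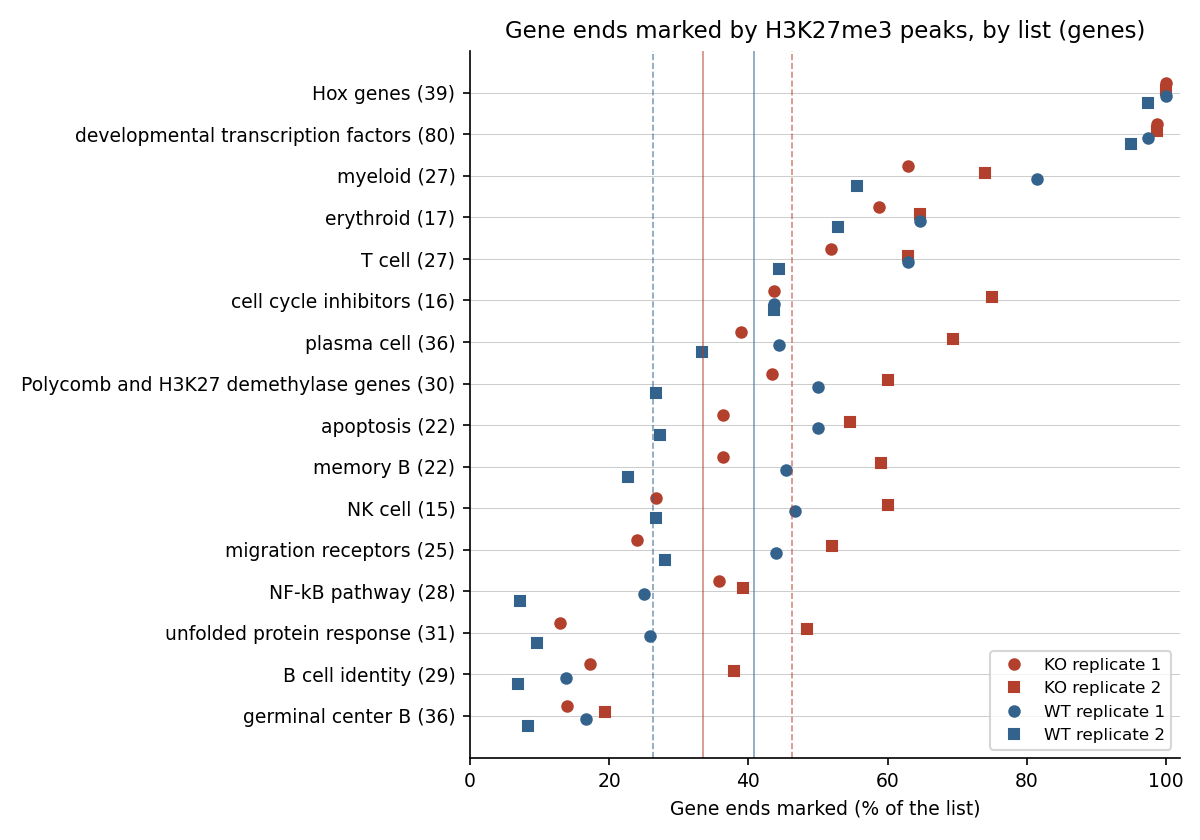
Percent of gene ends marked by H3K27me3 in each gene list, with the number of genes in parentheses. Red points are KO and blue points WT (circle replicate 1, square replicate 2), each for a single library, and vertical lines give the share of all genes in each library (solid replicate 1, dashed replicate 2). Hox genes and developmental transcription factors sit near 100% in all 4 libraries, and KO replicate 2 is the highest library for most lists.

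Regions present in only one genotype resembled the merged regions as a whole in length and were shorter than those called in every library. There were 4038 regions in both KO and neither WT, with a median length of 1455 bp, and 2118 in both WT and neither KO, with a median of 1363 bp. Gene ends were met by 16.3% of the former, 10.1% of the latter, 31.8% of regions called in all 4 libraries and 18.0% of all regions. For these shares the windows at both ends of every gene were counted, not the chosen end alone. The median length of all regions was 1464 bp. The longest KO-only region spanned 6085 bp on chromosome 7 (117317417 to 117323501), 57478 bp from Xylt1. It was followed by regions on chromosome 2 (73397402 to 73402496, 10881 bp from Gpr155), chromosome 2 within Slc43a1 (84850727 to 84855792), chromosome 19 (21518983 to 21523966, 46322 bp from Gda) and chromosome 13 (44251103 to 44256071, 447970 bp from Cd83). The longest WT-only region overlapped Plxna2 on chromosome 1 (194796641 to 194802936, 6296 bp). Others overlapped Padi3 on chromosome 4 (140798319 to 140803990), Ckmt2 on chromosome 13 (91873737 to 91878608) and Kcnq1 on chromosome 7 (143341371 to 143345768), and 1 lay on chromosome 17 (74480266 to 74484717), 4776 bp from Yipf4. In each of the 5 KO-only regions KO replicate 2 covered at least 93.8%, while KO replicate 1 covered 12.2% to 42.5%. In the 5 WT-only regions WT replicate 1 covered 77.4% to 100% and WT replicate 2 covered 13.4% to 38.8%.

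The split by genotype did not give the most group-specific regions. Separating KO replicate 2 and WT replicate 1 from KO replicate 1 and WT replicate 2 gave 10457 and 934 regions, and the remaining split gave 2658 and 2890. At equal covered length the genotype counts turned to 1042 KO-only and 2581 WT-only regions. Without WT replicate 2 they were 5585 and 15944. A WT-only region then needed a single WT library, while a KO-only region still needed both KO libraries, so these counts are not on equal terms. Equal covered length also turned the mixed split, to 653 regions for KO replicate 2 with WT replicate 1 and 7163 for KO replicate 1 with WT replicate 2, so the turn was not particular to genotype.

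At gene ends, more genes were marked in both KO and neither WT than the reverse, 262 against 41. The largest KO-only difference was at Mag, which encodes a myelin protein, with 98.1% ± 2.70 in KO and 18.3% ± 9.14 in WT (difference 79.8 points, SE 6.48). Cd40, the receptor through which T cell help reaches B cells, had 57.0% and 92.6% in the KO libraries and 0% in both WT libraries (difference 74.8 points, SE 15.3). Coro2a had a difference of 72.8 points (SE 18.7) and Ifit1, an interferon-induced gene, one of 71.4 points (SE 11.5). Lyg2, Myrfl, Eif4g3, Fzd10, Csf2rb, Tssc4, Tmprss4 and Maff followed with 52.0 to 66.9 points. The limma adjusted p was 0.895 for all 12. These patterns concern the gene-end window alone. Over the gene body, both WT libraries had coverage at Mag, Cd40, Coro2a, Lyg2, Myrfl, Tssc4 and Tmprss4. WT replicate 1 alone did at Csf2rb and Maff, and neither did at Ifit1, Eif4g3 and Fzd10. At Lyg2, Myrfl and Tmprss4 the body was covered to 58.1%, 58.0% and 78.8% in WT replicate 1. It was 40.8%, 40.8% and 50.7% in KO replicate 1 and 70.2%, 57.4% and 82.6% in KO replicate 2.

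Among genes marked in WT alone, the largest difference was at Adgrf5, an adhesion G protein-coupled receptor gene, with 0% in both KO libraries and 50.2% ± 5.74 in WT (difference -50.2 points, SE 4.64). Krtap10-10, Iqca, Xlr4a, Akr1b7, Ly6g, Cbln2, Fcho1, Wfdc13, Cfap52, Macc1 and Cst12 followed, with differences of -47.6 to -33.5 points and a limma adjusted p of 0.895. Xlr4a and Krtap10-10 belong to multigene families with near-identical copies, so reads there are uncertain. Cbln2, a synaptic organizer gene, had 46.3% and 46.5% in the WT libraries and 0% and 16.02% in the KO libraries. Over the gene body, both KO libraries had coverage at Xlr4a, Akr1b7, Cfap52 and Macc1. A single KO library did at Adgrf5, Ly6g, Cbln2 and Fcho1, and neither did at Krtap10-10, Iqca, Wfdc13 and Cst12.

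**Figure D3:**
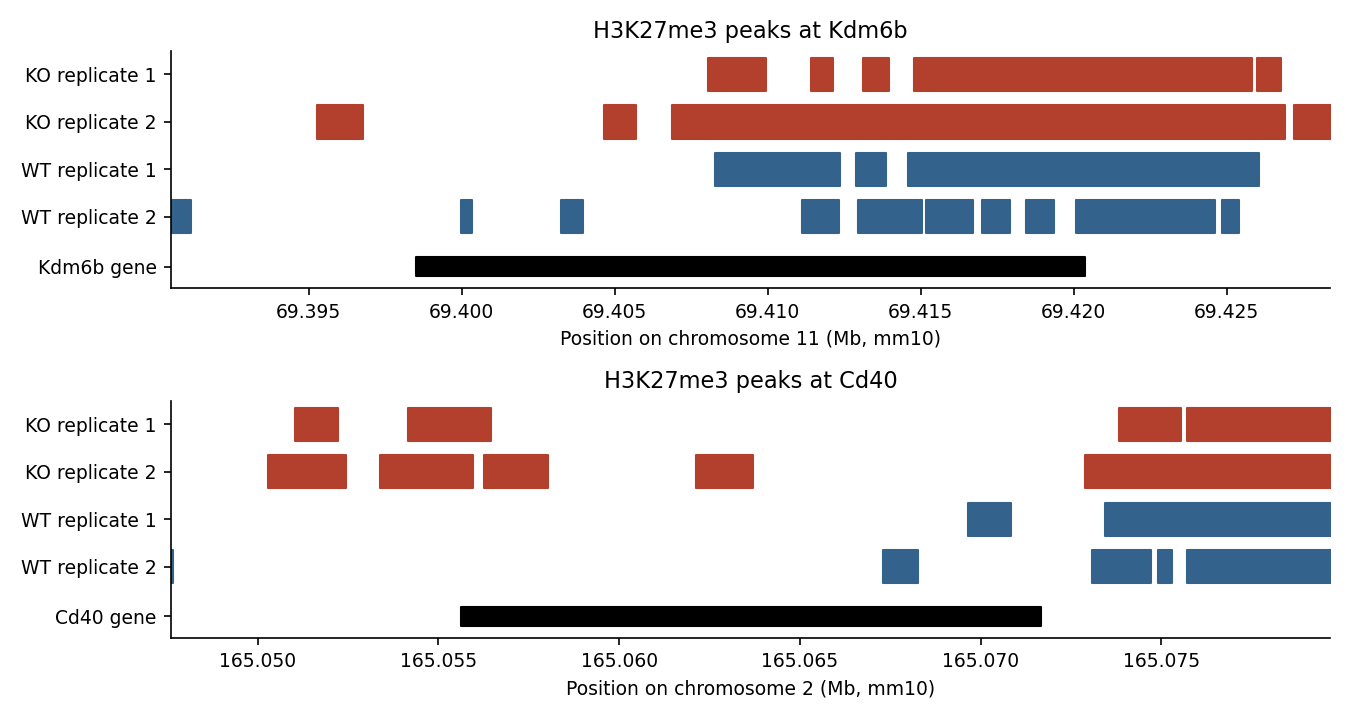
H3K27me3 peaks of each library around Kdm6b on chromosome 11 and Cd40 on chromosome 2, with position in Mb on mm10. Each bar is a deposited peak (KO red, WT blue) and the black bar is the gene. Both KO libraries and neither WT library have peaks at the lower end of Cd40, while all 4 have peaks beyond its upper end.

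The count of 262 did not exceed that of every other split, since 1202 gene ends were marked in KO replicate 2 and WT replicate 1 alone. Without WT replicate 2 there were 299 KO-only and 623 WT-only gene ends. These are not on equal terms, as WT-only then needed a single library and KO-only still both. At equal covered length the genotype counts were 169 and 125, and 37 of the 262 and 6 of the 41 genes kept their pattern, with Coro2a and Cbln2 the only such genes among the 24 named above. Cd40 turned to -9.42 points with 5000 bp to each side, where the other gene end was taken, Tssc4 to -22.1 with 1000 bp and -9.12 at equal covered length, Macc1 to 2.62 with 5000 bp, and Myrfl to 0 at equal covered length. The gene end was chosen anew for each peak list and window size, so a lost pattern can also reflect another window. At equal covered length Tssc4 was measured at its other end. There WT replicate 2, which kept all its peaks, had 18.25% against 17.15% before.

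**Figure D4:**
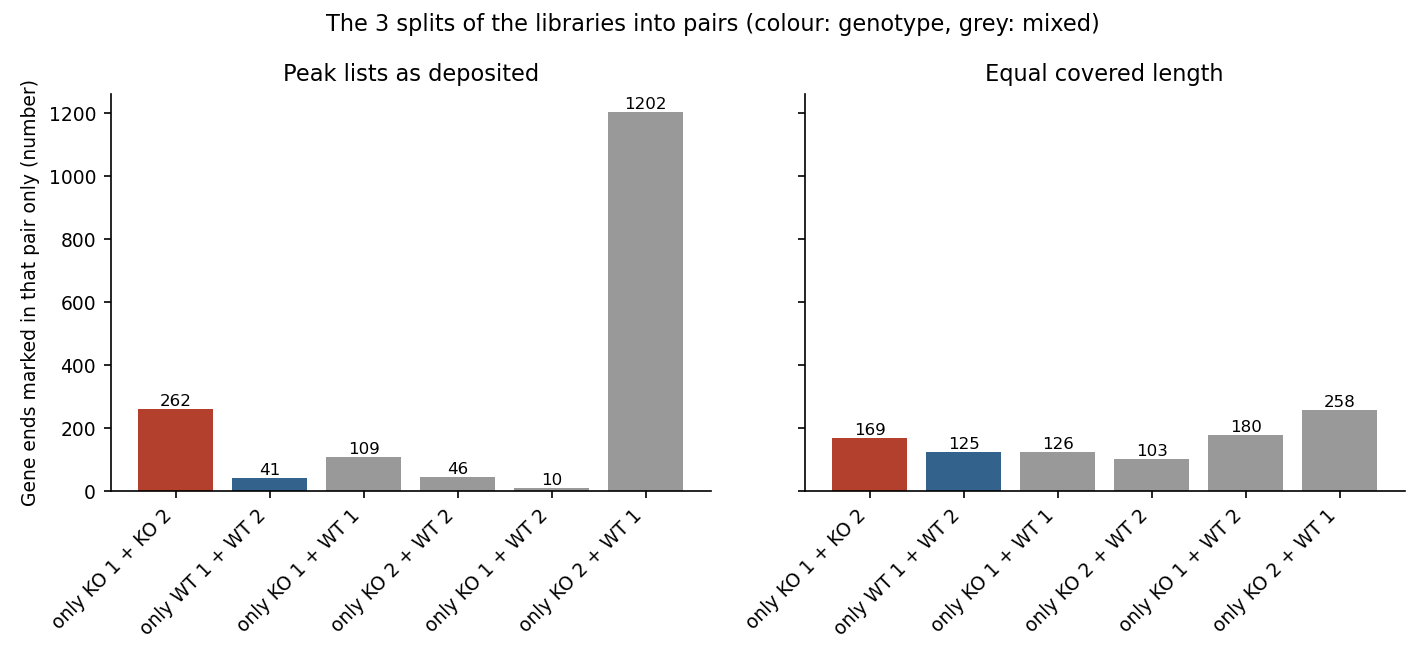
Number of gene ends marked in both libraries of a pair and in neither of the other pair, for the 3 ways to split 4 libraries into pairs. Coloured bars are the split by genotype and grey bars the mixed splits, for the deposited lists (left) and at equal covered length (right). The 262 KO-only gene ends stand beside 1202 for KO replicate 2 with WT replicate 1, and the counts draw together at equal covered length.

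No gene end and no window passed the test of genotype. Of 13844 gene ends with coverage in any library, 0 were higher and 0 lower in KO by limma at an adjusted p of 0.05 (smallest adjusted p = 0.895), and at an unadjusted p under 0.05 there were 490 higher and 66 lower. These unadjusted counts were 430 and 222 at equal covered length and 371 and 213 with covered length as a covariate. The mean difference over the 13844 gene ends was 7.41 points in favour of KO, ranging from -1.52 without WT replicate 2 to 17.0 without WT replicate 1. Both KO values lay above both WT values at 14.4% of gene ends and below at 2.26%, where chance gives 33.3% for the directions together if values are not tied. Of 68542 windows of 10 kb, 0 passed in either direction, with 691 higher and 34 lower at an unadjusted p under 0.05. At equal covered length these unadjusted counts were 1155 and 1124, and with covered length as a covariate 2475 and 2827, so the excess in KO did not hold. With the covered length of each library as a covariate, 37 windows were higher and 12 lower, on 1 residual degree of freedom. With noise drawn from the difference between KO replicate 2 and WT replicate 1, the same test called 0% of simulated changes of 60 points. That noise is not the spread within genotypes, so it does not set the size that could be detected. With 2 mice per genotype, the lack of calls does not show that the mark was unchanged.

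Over whole gene bodies in place of gene ends, 2 olfactory receptor genes were higher in KO, Olfr263 on chromosome 13 (21132777 to 21133730) and Olfr694 on chromosome 7 (106688782 to 106689729). Both were covered to 100% in each KO library and 0% in each WT library (limma adjusted p = 0.0380). They are short genes with no spread within either genotype, so their limma p rests on the spread shared by all genes. They belong to a family with many close copies, so reads there are uncertain.

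Across the gene lists, covered shares were on average higher in KO for all 16, as they were for all gene ends, and no list passed the test against other genes. The memory B list had the largest difference, with a mean of 21.9 points over 15 measured genes (camera adjusted p = 0.143, and adjusted p = 0.970 with an estimated correlation). Its members Tle3, a corepressor gene, and Bcl2, which protects cells from apoptosis, were covered to 88.0% ± 17.0 and 92.1% ± 11.2 in KO and 23.8% ± 33.6 and 52.7% ± 56.5 in WT (SD, n = 2). For Bcl2 the WT values were 92.7% and 12.8%, so WT replicate 2 alone set the difference. Nt5e, the surface enzyme CD73 of memory B cells, had 95.4% ± 6.51 and 65.5% ± 4.19. Of the 15 genes, 13 had a higher mean in KO and 6 lay above both WT values in both KO libraries. The 22 genes listed had 9 entries in other lists. The mean was 10.8 points without WT replicate 2 and 32.9 without WT replicate 1. At the preset correlation the adjusted p was 0.000431 with 5000 bp to each side, 0.0171 with both gene ends averaged and 0.0450 among gene ends with a mean covered share of at least 10%, but 0.266 with 1000 bp, 0.136 over gene bodies and 0.296 with the stricter peak list.

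The NF-kB pathway list, whose genes relay signals from receptors such as CD40, had a mean difference of 18.6 points over 21 genes (camera adjusted p = 0.245, and adjusted p = 0.970 with an estimated correlation). Marked in both KO and neither WT were Cd40, Ikbkb, which encodes a kinase that activates NF-kB, Bcl10, an adaptor in antigen receptor signalling, and Tnfrsf13c, the receptor for the survival factor BAFF. Tnfrsf13c was covered to 29.0% ± 1.52 in KO and 0% in both WT libraries, and Ikbkb to 39.1% ± 17.1 and 0%. At equal covered length Tnfrsf13c kept these values, Ikbkb had 0% in every library, Cd40 had 0% in KO replicate 2, and Bcl10 had means of 12.2% in KO and 17.1% in WT. The list reached an adjusted p of 0.0450 among gene ends with a mean covered share of at least 10% and 0.0469 with both gene ends averaged, but 0.394 with 5000 bp to each side, and its mean was 9.92 points without KO replicate 2 and 30.1 without KO replicate 1.

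Plasma cell genes had a mean difference of 11.5 points over 30 genes (camera adjusted p = 0.245, and adjusted p = 0.970 with an estimated correlation), which was 2.19 points without KO replicate 2 and 22.0 without KO replicate 1. They were marked at 14 and 25 of 36 in KO and 16 and 12 in WT, with a share above that of all genes in 4 of 4 libraries that passed the test in KO replicate 2 (Fisher's exact test, adjusted p = 0.0269, and 0.552 to 0.898 in the others). Derl3, of endoplasmic reticulum-associated degradation, had 37.2% ± 0.106 in KO and 7.23% ± 10.2 in WT, and Mzb1, which aids antibody assembly, had 42.4% ± 18.2 and 13.1% ± 10.5. At equal covered length these means were 18.6% and 7.23% for Derl3 and 25.6% and 13.1% for Mzb1, and neither kept its pattern. B cell identity genes were marked at 5 and 11 of 29 in KO and 4 and 2 in WT, with a share below that of all genes in 4 of 4 libraries that passed in WT replicate 1 (adjusted p = 0.0111, and 0.0551 to 0.650 in the others, Fisher's exact test). Among them Ms4a1, which encodes CD20, had 37.7% ± 5.90 in KO and 7.16% ± 10.1 in WT, and the transcription factor gene Ets1 had 39.1% ± 13.1 and 8.21% ± 11.6. Neither kept its pattern at equal covered length, with means of 16.8% and 7.16% for Ms4a1 and 9.40% and 0% for Ets1. Their mean difference was 14.4 points over 18 genes (camera adjusted p = 0.355, and adjusted p = 0.970 with an estimated correlation). It ranged from 8.81 points without KO replicate 2 to 23.5 without KO replicate 1, where alone it passed (camera adjusted p = 0.0182, against 0.426 to 0.867 on leaving out the others).

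The remaining lists also missed the camera threshold. Unfolded protein response genes were marked at 4 and 15 of 31 in KO and 8 and 3 in WT, with a share below that of all genes in both WT libraries and KO replicate 1, which passed in KO replicate 1 (adjusted p = 0.0441, and 0.0970 to 0.900 in the other libraries, Fisher's exact test). Polycomb and H3K27 demethylase genes were marked at 13 and 18 of 30 in KO and 15 and 8 in WT. Cell cycle inhibitors were marked at 7 and 12 of 16 in KO and 7 and 7 in WT, apoptosis genes at 8 and 12 of 22 and 11 and 6, and migration receptors at 6 and 13 of 25 and 11 and 7. In the germinal center list Ung, a DNA repair gene of antibody diversification, was marked in WT alone, with 20.6% ± 1.03 in KO and 29.8% ± 3.32 in WT. In the myeloid list Ly6g, a neutrophil marker, was marked in WT alone, with 10.9% ± 15.5 in KO and 49.8% ± 10.9 in WT. At equal covered length neither kept its pattern, with means of 10.6% in KO and 13.7% in WT for Ung and 0% and 21.1% for Ly6g. The gene body of Ly6g was covered to 0% and 64.5% in KO replicates 1 and 2 and to 33.5% and 24.2% in WT replicates 1 and 2.

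In none of the 16 lists did a member pass 0.05 adjusted over the list alone or over all genes tested, where limma called 0 in each. For germinal center B, unfolded protein response, Hox, developmental, T cell, NK cell and myeloid genes camera's moderated statistic gave the direction as lower than other genes, without passing, while their mean differences were positive, from 2.73 to 9.68 points. The Hox median difference was 0 and the other medians were positive. Hox and developmental gene ends, with mean shares of 94.0% and 89.9% in WT, had little room to rise. For germinal center B and NK cell genes the mean differences of 7.53 and 9.68 points even lay above the 7.41 points of all gene ends, against the direction of the statistic.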

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

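No test in this part was chosen after the result was seen. Each peak list also held peaks outside chromosomes 1 to 19, X and Y, which no comparison used: 56 in KO replicate 1, 78 in KO replicate 2, 66 in WT replicate 1 and 66 in WT replicate 2. They were picked out as signal in data left out of the comparisons, with no control library to set a background. They lay on 17 to 25 sequences per library and included 3 peaks on the mitochondrial genome in each KO library and 2 in each WT library. Mitochondrial DNA carries no histones. No explanation was tested for these peaks.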

How the results depend on the processing

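Equal covered length, covered length as a covariate and both gene ends averaged were chosen after the data were seen. No paired analysis was possible because the replicate numbers follow accession order only and pair no mice. The limma count of 0 gene ends higher or lower held under every alternative run, except for 2 higher over gene bodies. The count of 0 windows held under every one except the covariate, with 37 higher and 12 lower. KO-only regions numbered 1042 at equal covered length and 2547 with peaks closer than 1000 bp merged, against 4038. KO-only gene ends, 262 as reported, numbered 169 at equal covered length, 405 with any overlap, 162 at 50% covered, 164 with 5000 bp to each side and 167 with both ends averaged. WT-only gene ends, 41 as reported, numbered 125, 94, 10, 14 and 16 under the same alternatives. The X share difference turned to -0.0199 points at equal covered length. Lists passing camera numbered 2 among gene ends with at least 10% mean coverage (memory B and NF-kB), 1 with 5000 bp (memory B) and 2 with both ends averaged (memory B and NF-kB). These calls use the preset correlation, and with an estimated one both lists had an adjusted p of 0.970 on the reported windows. Mean list differences turned to -2.87 points for the unfolded protein response and -5.81 for NK cell at equal covered length, and to -2.19 for myeloid with the covariate. The cause was not tested for these. For the 24 genes of the genotype patterns, 211 of 216 values under alternatives kept their direction. These genes were picked for large differences in the same lists, so kept directions are no independent support. At equal covered length 1 of 12 kept its pattern in each direction.

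Leaving out a library leaves a lone mouse in its group, assumed to vary like the others. KO-only regions then ranged from 5585 to 22536, WT-only regions from 3161 to 15944, KO-only gene ends from 299 to 1871 and WT-only gene ends from 57 to 623. These counts grow by construction, as fewer libraries must match. Without WT replicate 2 the order turned, with 299 KO-only and 623 WT-only gene ends, and likewise for regions, with 5585 and 15944. WT-only then needed a single library, while KO-only still needed both KO libraries. The turn in these counts may thus arise by construction. The difference in peak number (KO minus WT) ranged from -4250 to 5528 and in covered length from -22.8 to 88.5 Mb, both below 0 without KO replicate 2 or WT replicate 2. Lists passing camera ranged from 0 to 3, the 3 arising without KO replicate 1 (B cell identity higher, Hox and developmental factors lower than other genes) at the preset correlation. With all libraries and an estimated correlation, each of these lists had an adjusted p of 0.970. Hox and developmental gene ends were near full coverage in WT, with mean shares of 94.0% and 89.9%. They had little room to rise, so a direction lower than other genes does not show a loss of the mark. Mean list differences ranged from -1.47 to 16.02 points for the unfolded protein response, -3.28 to 14.6 for migration receptors, -0.20 to 5.66 for Hox, -4.32 to 14.6 for T cell, -5.34 to 24.1 for NK cell, -11.0 to 23.9 for myeloid and -3.37 to 14.4 for erythroid genes. All were lowest without WT replicate 2, except the unfolded protein response and NK cell, lowest without KO replicate 2. The lists without a turn in sign ranged, for example, from 2.19 to 22.0 points for plasma cell and from 10.8 to 32.9 for memory B genes. The cause of these turns was not tested.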

Other observations

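The tests of covered length on the genotype counts and both tests of the memory B list were chosen only after the result was seen, and the matched sets for constitutive genes after their ratio was seen. Of the 22 genes in the apoptosis list 6 were marked in all 4 libraries and 9 in none. The genes named in the rest of this paragraph were chosen after their values were seen, for high coverage in every library. The apoptosis inducers Bik, Bcl2l11 and Hrk had gene-end windows covered to 100% ± 0, 97.9% ± 2.97 and 95.2% ± 1.31 in KO and 100% ± 0, 89.1% ± 1.84 and 94.9% ± 0.495 in WT (SD, n = 2). Among cell cycle inhibitors, Cdkn2b had 100% ± 0 and 95.1% ± 6.99, and Cdkn1c had 100% ± 0 and 91.2% ± 12.5. The plasma cell homing receptor gene Ccr10 had 100% ± 0 and 94.98% ± 7.11, and Fkbp11, of the secretory pathway, had 100% ± 0 and 98.5% ± 2.09. Among 222 genes of 7 constitutive families, such as ribosomal and proteasome proteins, 16.2% of gene ends were marked in KO replicate 1, 32.0% in KO replicate 2, 23.0% in WT replicate 1 and 6.76% in WT replicate 2.

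The highest peak of every library lay at one place on chromosome 2, at 98666231 to 98667336 in KO replicate 1. Its highest coverage was 33765, 55058, 25598 and 32177 steps in KO replicates 1 and 2 and WT replicates 1 and 2, and it held 0.204%, 0.300%, 0.121% and 0.286% of total signal. Peaks were not filtered for repeated sequence here, so it is not known whether this place carries the mark.

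More gene ends were marked in both KO and neither WT than the reverse, 262 against 41, a ratio of 6.39. With every library held to one covered length the ratio was 1.35, in keeping with the hypothesis that the difference in covered length between libraries may account for most of the excess. The test could have left the ratio above 3, and did not, though it also removes the lower peaks of the broad libraries. A loss of Kdm6b activity that spreads the mark over more of the genome stays open, since it would raise covered length too, and covered length was 190 ± 65.0 Mb in KO and 157 ± 78.6 Mb in WT with an exact permutation p of 0.667.

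KO replicate 2 had the most gene ends marked, 10128 of 21887. At the 26992 regions shared by all libraries its median highest coverage was 71.0 steps (quartiles 52 to 104) against 96 to 97 in the others. That met the outcome set in advance as speaking against greater depth, a median below at least 2 other libraries. Greater depth is still left open here, on grounds outside that rule. The quartile ranges overlap, and the scale of a step is unknown. At the highest peak of every library KO replicate 2 had 55058 steps against 25598 to 33765. That is a single place, not known to carry the mark, so it says little on depth. The marked share of constitutive genes in this library was 2.09 times the mean of the other libraries (95% bootstrap interval 1.69 to 2.62 over genes) against 1.38 for all genes. A set that starts low can gain by ratio whatever its genes are, and at 32.0% marked these genes equalled the median of 32.0% of 10000 random sets matched on covered share in the other libraries (central 95% of sets 27.5% to 36.5%), so a special gain at constitutive genes is argued against, and peak calling over open gene ends cannot be told apart from a wider spread of peaks. Its calling threshold, with a lowest maximum of 13 steps against 20 to 22 elsewhere, was not tested, and biological variation between mice stays open.

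The memory B list had the highest mean difference in covered share of the 16 lists. At equal covered length its excess over all genes was 17.3 points, with an SE of 7.50 over genes taken as independent and 17.6 with their estimated correlation of 0.373, so covered length as the cause stays open. On leaving out a library the excess was 15.19 points without KO replicate 1, 15.41 without KO replicate 2 and 15.97 without WT replicate 1. It was lowest without WT replicate 2, at 12.4 points (SE 4.28 over genes, and 10.7 with that correlation). The excess thus stayed positive and similar in size without any one library, which argues against a single library deciding it. With that correlation the SEs were 10.7 to 17.6 points, so chance stays open. The camera adjusted p was 0.143, and 0.130 at equal covered length, and the list was singled out of 16 after its values were seen. That H3K27me3 may extend further over memory B genes in the knockout is thus a hypothesis. With 2 mice per genotype it cannot be told apart from an effect of covered length or from chance.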
